A study of Mus musculus with 2 samples.

How the data were processed

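H3K9ac was measured by chromatin immunoprecipitation and sequencing in hindbrain of mouse embryos of 12.5 days, in 1 group of 2 biological replicates, which the labels describe as separate pools of 120 and 88 embryos of mixed sex. The labels give a library size range of 300 to 500 bp for both. The series deposits peak lists on the mm10 build, per the labels: a list for each replicate, a list called on both replicates together (the pooled list) and a list of replicated peaks. Per the file lists deposited with each sample, each replicate's peaks were called against a control alignment of its own, and the replicated list was derived from the pooled list and the replicate lists. The aligner, the peak caller, its settings and the rule for replicated peaks are not given in the sources used here, and the control data were not analysed here.

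Each peak has 4 values made by the authors, in the order of the narrowPeak format. The enrichment of the peak is the deposited narrowPeak signal value. Its unit is not given, and it was read here as an enrichment and used only to rank peaks within a list. The significance of the peak is deposited as a −log10 p and a −log10 q value, of which the −log10 p was used only to rank the peaks of the replicate lists. The position of the summit is deposited in bp from the peak start. Because the files give no read counts, the depth of each library is unknown, and no interval that needs it was computed. Confidence intervals on shares of peaks are exact Clopper-Pearson intervals at 95% and cover counting error only, with peaks treated as independent. What was measured of the replicated list is that all 35337 of its peaks are in the pooled list with identical values, that 28377 (80.3%) overlapped both replicate lists by at least 1 bp, 6558 (18.6%) a single one and 402 (1.14%) neither, and that it held all 28188 pooled peaks that met 50% of either peak in both replicate lists.

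Genes, transcripts and start sites were taken from GENCODE release M21 on GRCm38.p6, the same coordinates as mm10. In the build check, 99.9% of 27337 annotated start codons read ATG in the genome sequence and 0 peaks ended past their chromosome. All 21853 protein-coding genes on chromosomes 1 to 19, X and Y were used, with 54361 distinct start sites of their protein-coding transcripts, and peaks on unplaced scaffolds were left out of the comparisons. Coordinates are printed 1-based. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and bedtools 2.31.1.

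Peaks of the replicates were called shared when they overlapped by at least 1 bp. Chance overlap came from 100 shuffles of the replicate 2 peaks within their chromosomes, with assembly gaps excluded. Each replicated peak was placed by its summit, in promoters (1000 bp on either side of a protein-coding TSS), then exons, introns and intergenic sequence, beside 100 shuffles of the list. A gene was called marked when a replicated peak overlapped the promoter window of any of its start sites. Promoter CpG content was the observed over expected CpG frequency within 1000 bp of the gene 5′ end, which is not always the marked start site.

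The 27 gene lists and the tests on them described here were fixed before the data were examined. The lists cover Hox paralog groups 1 to 4, 5 to 8 and 9 to 13, patterning genes, forebrain transcription factors, neural progenitors, dorsoventral and proneural factors, neuron subtype factors, pan-neuronal and neurotransmitter genes, glia, roof plate and choroid plexus, endothelium, erythroid cells, microglia and leukocytes, mesenchyme, muscle, liver and gut, epidermis, germline, cell cycle, histone acetylation, immediate early, ribosomal protein, proteasome, olfactory receptor and vomeronasal receptor genes. All 376 members listed by name were in the annotation, and the last 4 lists were taken by symbol pattern. Each list's share of marked genes was set against all other protein-coding genes with a two-sided Fisher exact test, adjusted by Benjamini-Hochberg over the 27 lists. Breadth was the number of base pairs covered by replicated peaks within 5000 bp of the gene 5′ end, and the median over a list's marked genes was set against 10000 random draws of as many marked genes (two-sided permutation test, lists with at least 5 marked genes). Distal peaks lay entirely more than 5000 bp from any protein-coding TSS and were given to the nearest one within 100 kb of the summit, and their mean per gene was set against 10000 random draws of genes. The threshold was an adjusted p of 0.05, and the smallest p that these draws can give is 0.0002. With 1 group there was no comparison between groups, and no p across libraries was computed. Spread between replicates is given as the SD of the values from the 2 replicate lists.

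The genes named in the text followed a rule fixed beforehand: up to 2 marked members of each list with the highest enrichment and up to 2 unmarked members in alphabetical order, any Hox gene, 1 of each kind for lists taken by symbol pattern, the 10 genes with the most covered bases, and the 10 strongest distal peaks with their nearest gene. Other non-coding genes, and other genes in the closing section, were named after their values were seen.

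The tests were run on simulated data first, with 10 changed and 10 unchanged lists drawn among 21853 genes for each. The marking test called 9 of the 10 changed lists and 0 of the unchanged, the breadth test 10 and 0, and the distal test 10 and 1. The changed lists were given large effects, so power for smaller ones was not tried. For the overlap rules, 60.0% of simulated peaks were exact copies and the rest touched no original peak. The recovered share of 60.0% was therefore fixed by design and says nothing about partial overlaps.

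The alternatives tried were other overlap rules, −log10 q limits of 2 and 5, equal numbers of the strongest peaks, each replicate left out in turn, all pooled peaks, pooled peaks in both replicates, windows of 500 and 2000 bp, gene 5′ ends only, distal limits of 2000 bp and 1000000 bp, and random lists matched on decile of promoter CpG content or of the distance to neighbouring start sites. Alternatives and tests added after the data were seen are named as such in the closing section. Leaving out 1 of 2 replicates means using the list of the other replicate alone.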

Results

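Acetylation of lysine 9 on histone H3 (H3K9ac), a mark of active promoters and some enhancers, was mapped by chromatin immunoprecipitation and sequencing in mouse hindbrain at 12.5 days of embryonic development. There was 1 group with 2 biological replicates, hindbrains pooled from 120 embryos for replicate 1 and from 88 embryos for replicate 2. The labels state no contrast, so the question addressed here was where the mark lay in this tissue and at which genes. The data were peak lists on the mm10 build. The list of replicate 1 held 65104 peaks with a median width of 273 bp, and the list of replicate 2 held 75942 peaks with a median width of 240 bp. These lists covered 34.9 and 34.8 Mb of the genome. The pooled list, called on both replicates together, held 78916 peaks, and the replicated list, a subset of the pooled list selected by the authors, held 35337 peaks with a median width of 670 bp that covered 34.3 Mb. The read depth is unknown because the files give no read counts. Each peak carries the authors' signal value, called enrichment here, which ranks peaks within a list and is not compared between lists.

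The strongest H3K9ac peaks were found in both hindbrain pools, and the weakest were mostly found in 1 of them. Every peak in the top decile by enrichment was overlapped in the other replicate (100% of either list), against 23.5% of the lowest decile in replicate 1 and 16.6% in replicate 2. The promoter peaks of Msi1, which encodes a neural stem cell RNA-binding protein, of Tnrc18, and of Pbx3, a cofactor of Hox proteins, were strong and present in both replicates, with enrichment values of 36.8, 37.8 and 28.7 in the replicated list. By contrast, Hoxd10, with a weak replicated peak (2.84), had a peak over the promoter window in the replicate 2 list only. So did Hoxb9 (3.26), although a replicate 1 peak of 170 bp overlapped its replicated peak outside the window. Over all peaks, 50.2% of the replicate 1 list overlapped the replicate 2 list by at least 1 bp (95% exact Clopper-Pearson interval 49.8 to 50.6%). In the other direction the share was 46.0% (45.7 to 46.4%). Shuffled peaks gave 3.26 ± 0.08% and 2.61 ± 0.06% (mean ± SD over 100 shuffles within chromosomes), so the observed shares were 15.4 and 17.6 times higher. In base pairs the lists shared 48.2% of their union, against 0.768% after shuffling. Across 32699 shared peaks the enrichment values of the replicates had a Spearman rho of 0.76, a correlation across peaks, which are not independent replicates. The share depended on the rule and the peak strength: among peaks with a −log10 q of at least 5 in both lists, 78.6% of the replicate 1 list and 91.7% of the replicate 2 list were shared, and with a reciprocal overlap of 50% the shares were 33.7 and 28.9%.

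**Figure D1:**
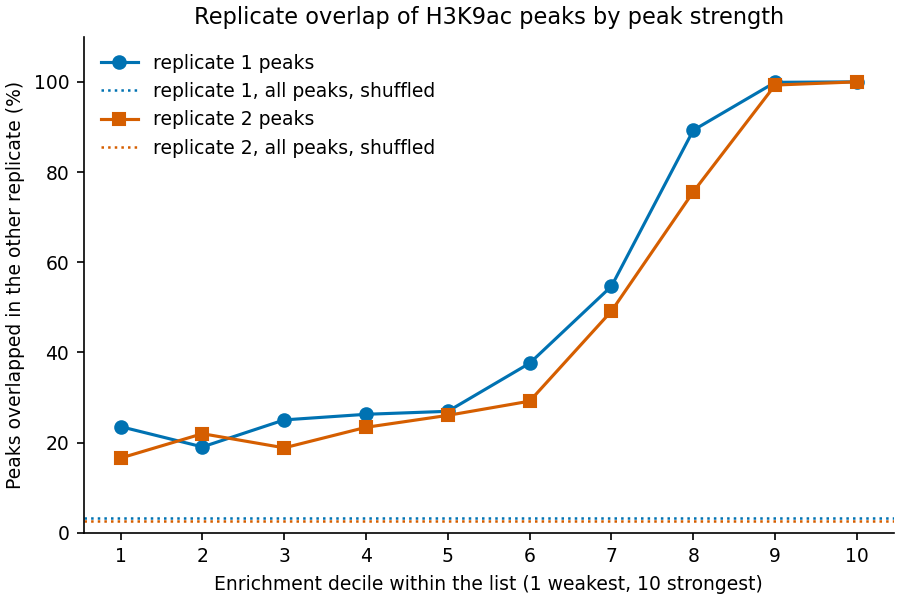
Share of peaks overlapped by at least 1 bp in the other replicate (y axis, %) by decile of the enrichment value within each list (x axis, 1 weakest), for replicate 1 (circles) and replicate 2 (squares), with the mean of 100 shuffles over all peaks as dotted lines. The shares run from 23.5 and 16.6% in the lowest decile to 100% in the highest.

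H3K9ac in the hindbrain was concentrated at the starts of protein-coding genes. Of the 35331 replicated peaks on the assembled chromosomes, 17057 (48.3%) had their summit within 1000 bp of an annotated transcription start site (TSS) of a protein-coding gene, against 2.73 ± 0.08% of shuffled peaks, a 17.7-fold excess. Exons outside these windows held 5.64% of the summits (2.60% shuffled), introns 26.9% (37.3% shuffled) and intergenic sequence 19.2% (57.4% shuffled). Peaks with a promoter summit were wide and strong, with a median of 1178 bp and an enrichment of 9.27. The 11776 peaks more than 5000 bp from any protein-coding TSS had a median of 428 bp and an enrichment of 3.40. The promoter share depended on the list. It was 32.7% in the replicate 1 list and 29.8% in the replicate 2 list (mean 31.2 ± 2.08%, SD, n = 2), and 26.5% in the pooled list. In each of these lists it stayed above the 2.73% of the shuffled replicated list.

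**Figure D2:**
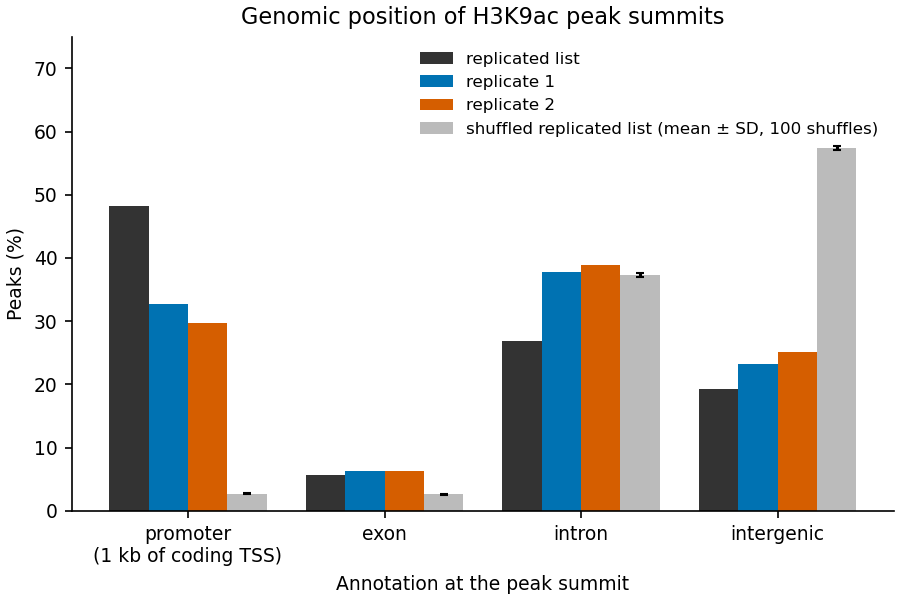
Share of peak summits (y axis, %) in promoters, exons, introns and intergenic sequence for the replicated list, the list of each replicate, and 100 shuffles of the replicated list (mean with SD bars). Promoters hold 48.3% of replicated summits, 32.7 and 29.8% in the replicates, and 2.73% after shuffling.

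A peak over the promoter window, 1000 bp on either side of any TSS of a protein-coding transcript, marked 14051 of 21853 protein-coding genes (64.3%). The replicate lists marked 65.7 and 66.1% (mean 65.9 ± 0.304%, SD, n = 2), and 948 genes (4.34%) were marked in 1 of the replicate lists only. Marking followed the CpG content of the promoter, measured as the observed over expected CpG frequency within 1000 bp of the gene 5′ end. In the CpG-poorest decile of genes 3.39% were marked, in decile 5 80.7%, and in the richest decile 98.99%. This dependence is the reason that each of the 27 gene lists below was also set beside random lists of the same CpG content at the gene 5′ end. Because marking counts any start site, this matching does not control for the number of start sites. Nor does it control for the CpG content at an inner marked start site.

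The Hox genes, which encode transcription factors that give cells their position along the head-to-tail axis, were marked more often in anterior than in posterior paralog groups. All 12 genes of paralog groups 1 to 4, whose expression reaches into the hindbrain, were marked, as were 9 of 11 genes of groups 5 to 8. Only 2 of 16 genes of groups 9 to 13, which act in the trunk, limbs and tail, were marked. The difference between groups 1 to 4 and groups 9 to 13 was 87.5 percentage points (two-sided Fisher exact p = 5.98e-06), and it was 81.3 points in the replicate 1 list and 68.8 points in the replicate 2 list. The test counts genes as independent, although they lie side by side in clusters, so its p may overstate the evidence. In the Hoxa cluster on chromosome 6 (52155590 to 52260880) all 4 genes of groups 1 to 4 and all 3 of groups 5 to 8 were marked and none of the 4 genes of groups 9 to 13. In the Hoxb cluster on chromosome 11 the counts were 4 of 4, 4 of 4 and 1 of 2, in the Hoxc cluster on chromosome 15 they were 1 of 1, 1 of 3 and 0 of 5, and in the Hoxd cluster on chromosome 2 they were 3 of 3, 1 of 1 and 1 of 5. A single peak of 25964 bp, the widest of the replicated list, ran over Hoxb3 (chromosome 11, 96321500 to 96347463, enrichment 13.7). Another of 12298 bp ran over Hoxa2, a selector gene of the second pharyngeal arch (chromosome 6, 52161716 to 52174013, enrichment 21.4). Both were split in the replicate lists, where the widest parts were 14357 and 7916 bp at Hoxb3 and 7562 and 7436 bp at Hoxa2. The unmarked genes of groups 5 to 8 were Hoxc6, which had a promoter peak in the replicate 2 list, and Hoxc8. The marked genes of groups 9 to 13, Hoxb9 and Hoxd10, had narrow peaks of 409 and 224 bp. Narrow peaks also counted in the other groups, such as 389 bp at Hoxb1 (enrichment 3.42) and 290 bp at Hoxa6 (3.88). The replicate lists marked 3 and 5 genes of groups 9 to 13 (18.8 and 31.3% of the group), among them Hoxa13 and Hoxd13 in replicate 1 and Hoxd9 and Hoxb13 in replicate 2. Against all other genes, groups 9 to 13 were marked less often (adjusted p = 0.000112, exact), and groups 1 to 4 more often (adjusted p = 0.0104, exact). Groups 5 to 8 did not pass (17.5 points, exact adjusted p = 0.427), and against CpG-matched lists their difference turned to -10.3 points (permutation adjusted p = 0.633, range over 10 alternatives 0.142 to 0.789). The call on groups 1 to 4 was lost among peaks with a −log10 q of at least 5 (exact adjusted p = 0.0613) and with only the gene 5′ end used (0.0569), with a range of 0.00737 to 0.0613 over 10 alternatives.

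**Figure D3:**
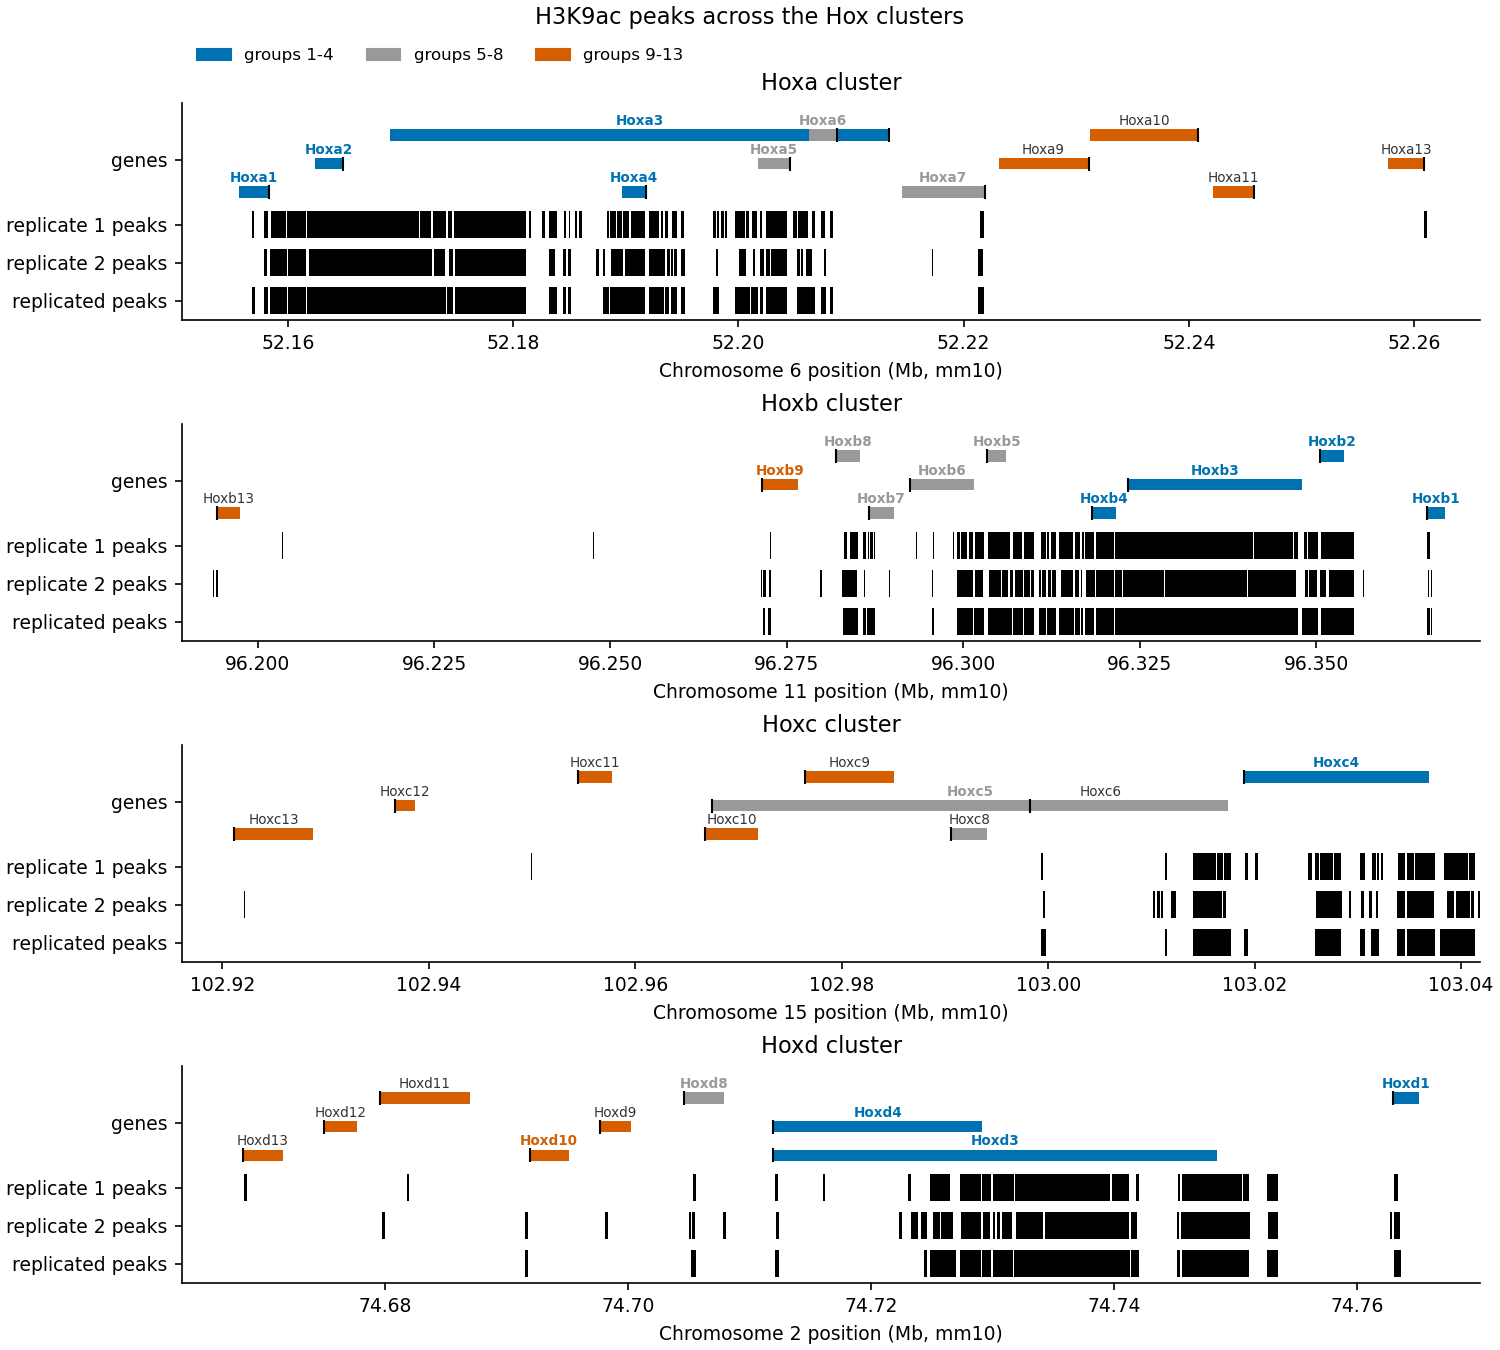
H3K9ac peaks (black bars) of replicate 1, replicate 2 and the replicated list across the 4 Hox clusters (x axis, position in Mb on mm10), with genes coloured by paralog group, a tick at each gene's 5′ end, and bold names for genes with a replicated peak at a promoter. Wide peaks lie over parts of groups 1 to 4. Few bases are covered around Hoxb1 and Hoxd1 and around the outermost 5′ ends of Hoxa3, Hoxd3 and Hoxd4. Replicated peaks over groups 9 to 13 are few and narrow.

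Genes that pattern the hindbrain and its progenitors carried the mark. Of 18 genes of the midbrain-hindbrain boundary and rhombomeres, 17 were marked (94.4%), with the highest enrichment at the Hox cofactors Pbx3 (28.7) and Meis1 (26.3, a peak of 9811 bp at chromosome 11, 19011962 to 19021772). The unmarked gene was Wnt1, a signal of the boundary itself, which had a promoter peak in the replicate 2 list only. All 18 neural progenitor genes were marked in the replicated list and in each replicate list, led by the RNA-binding proteins Msi1 (36.8, a peak of 9413 bp at chromosome 5, 115428104 to 115437516) and Msi2 (25.9). Both groups were marked more often than other genes, by 30.2 and 35.7 percentage points (two-sided Fisher exact tests, adjusted p = 0.0104 and 0.00142 over 27 lists). Both calls were lost against random lists matched on promoter CpG content, which had 93.5 and 89.2% of genes marked (permutation adjusted p = 1 and 0.123). Matched shares this high left the test little room to call a list. The progenitor list stood at the maximum of 100% and still missed the threshold. The lost calls therefore do not show that CpG content accounts for the marking. Over 10 alternatives the adjusted p ran from 0.00204 to 1 for patterning genes and from 0.000407 to 0.123 for progenitor genes.

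All 20 pan-neuronal genes were marked in both replicates, among them Elavl3 (enrichment 21.9), an RNA-binding protein of young neurons, and Rbfox3 (21.4), which encodes the neuronal marker NeuN. They were marked more often than other genes by 35.7 points (exact adjusted p = 0.000474) and than CpG-matched lists by 27.9 points (permutation adjusted p = 0.0009). Among transcription factors of hindbrain neuron subtypes 17 of 20 were marked, including Lhx5 (14.3) and Lhx1 (12.8), and Phox2b, a factor of visceral motor neurons, and Tbx20 were not. Phox2b had a promoter peak in the replicate 2 list. The subtype factors missed the threshold (exact adjusted p = 0.0926), and they passed it in all pooled peaks (0.00147), in the replicate 2 list alone (0.00754), with windows of 2000 bp (0.00704) and without shared promoter windows (0.0356), within a range of 0.00147 to 0.726. Against CpG-matched lists, of which 95.7% were marked, their difference turned from 20.7 to -10.7 points (permutation adjusted p = 0.161). Dorsoventral and proneural factors were marked at 15 of 19 genes (exact adjusted p = 0.301), including the proneural genes Ascl1 (14.4) and Neurog2 (11.02) and excluding the interneuron progenitor factors Dbx1 and Dbx2. Neurotransmitter genes were marked at 13 of 18 (exact adjusted p = 0.675). The GABA-synthesis gene Gad1 (8.66) and the glycine transporter gene Slc6a5 (8.38) carried peaks, and Dbh and Ddc, enzymes of catecholamine synthesis, did not.

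Forebrain transcription factors were marked at 15 of 21 genes (71.4%), 7.14 points above other genes (exact adjusted p = 0.675). Lhx2 (enrichment 9.005), a factor of cortical progenitors, and Dlx6 (6.52), a factor of the ventral forebrain, carried peaks in both replicates. Arx and Fezf2, factors of forebrain neurons, were unmarked in the replicated list and had a promoter peak in the replicate 1 list only. The replicate lists gave 76.2 and 66.7% (mean 71.4 ± 6.73%, SD, n = 2). Their promoters are rich in CpG, and against CpG-matched lists the direction turned: 89.7% of matched genes were marked, and the difference of the forebrain factors was -18.3 points (permutation adjusted p = 0.0335, range over 10 alternatives 0.0335 to 1). The dorsoventral and proneural factors turned in the same way, with a difference of -15.1 points from their matched lists (permutation adjusted p = 0.0403). With windows of 2000 bp those factors were instead called more often than other genes (exact adjusted p = 0.0426, range over 10 alternatives 0.0403 to 0.435).

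Genes of other lineages were marked less often or did not differ. Of 16 genes of astrocytes and oligodendrocytes, which mostly mature after this stage, 7 were marked (exact adjusted p = 0.156), including the glutamate transporter gene Slc1a2 (13.7) and the myelin gene Mbp (8.96) but neither Aldh1l1 nor the water channel gene Aqp4. Aldh1l1 had a promoter peak in both replicate lists and Aqp4 in the replicate 1 list, and these lists marked 9 and 8 of the 16 genes. Roof plate and choroid plexus genes were marked at 9 of 13 (exact adjusted p = 1), with Rspo3 (7.92) and Gdf10 (6.68) but not Aqp1 or Folr1. Endothelial genes were marked at 7 of 13 (exact adjusted p = 0.634), with the vascular growth factor receptor gene Kdr (7.59) and Erg (6.63) but not Cdh5 or Emcn. Mesenchyme, meninges and neural crest genes were marked at 12 of 16 (exact adjusted p = 0.521), with Twist1 (10.2) and Prrx1 (9.94) but not the matrix genes Col3a1 and Dcn, of which Dcn had a promoter peak in the replicate 1 list. Erythroid genes were marked at 5 of 13 (exact adjusted p = 0.111, and 0.0288 with windows of 500 bp, range 0.0288 to 0.816), with the transferrin receptor gene Tfrc (14.6) and Nfe2 (8.83) but not Alas2 or Epb42, of which Epb42 had a promoter peak in the replicate 2 list. Against CpG-matched lists the difference of the erythroid genes turned from -25.9 to 8.55 points (permutation adjusted p = 0.816), and that of the astrocyte and oligodendrocyte genes from -20.6 to 0.0838 points (1).

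In the replicated list, muscle, liver, germline and immune genes were marked least among the tissue lists. Liver and gut genes were marked at 1 of 17 (5.88%, exact adjusted p = 5.26e-06), and that gene, Foxa3, shares its peak of enrichment 19.6 with the promoter of Sympk. Albumin (Alb) and Apoa1 were unmarked. Germline genes were marked at 1 of 15 (6.67%, exact adjusted p = 2.93e-05), Dazl (4.66), and Ddx4, which had a promoter peak in the replicate 2 list, and Figla were not. Muscle genes were marked at 3 of 17 (17.6%, exact adjusted p = 0.000297), with weak peaks at the myogenic factor gene Myod1 (3.21) and the heart factor gene Hand2 (3.11, in replicate 2 only of the replicate lists) and none at the actin genes Acta1 and Actc1. These 3 lists also lay under their CpG-matched lists, with differences of -37.9, -53.9 and -34.7 points (permutation adjusted p = 0.0009, 0.0009 and 0.00154). Microglia and leukocyte genes were marked at 1 of 13 (7.69%, exact adjusted p = 0.000125), with a narrow peak at the B cell gene Cd19 (2.90) and none at the T cell gene Cd3e or the microglial gene Aif1, which had a promoter peak in the replicate 2 list. Epidermis genes were marked at 4 of 13 (30.8%, exact adjusted p = 0.0281), with Lor (11.95) and Grhl1 (9.002) but not Dsg1a or Dsg3. The Lor peak lay over its coding exon, and in neither replicate list did a peak reach the window. Outside epidermis, single replicate lists marked more genes: 29.4% of liver and gut genes, 35.3% of muscle genes and 13.3% of germline genes in replicate 2, and 38.5% of microglia and leukocyte genes in replicate 1, where that call was lost (exact adjusted p = 0.105, and 0.0855 with CpG matching, range 1.00e-05 to 0.105). In replicate 1 the liver and gut and germline shares were unchanged, at 5.88 and 6.67%. Epidermis genes were marked at 23.1% in each replicate list. The epidermis call was lost with CpG matching (permutation adjusted p = 0.945), with windows of 2000 bp (0.102) and without shared promoter windows (0.0668, lowest over 10 alternatives 0.00426).

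Housekeeping and immediate early genes were marked nearly throughout and sensory receptor genes almost never. All 24 genes for enzymes and partners that add or remove histone acetylation were marked, led by the deacetylase gene Hdac7 (26.5) and the acetyltransferase gene Ep300 (22.2). So were all 20 cell cycle genes, with the highest values at Aurka (12.7) and Mcm7 (12.3), which share their peaks with Cstf1 and Ap4m1, and all 13 immediate early genes, such as Dusp1 (15.5, shared with Ergic1) and Jun (14.4). Cytosolic ribosomal protein genes were marked at 79 of 82, with Rps24 at 27.01 and the retrocopy Rpl10l unmarked. Proteasome genes were marked at 37 of 39, with Psmd3 at 25.4 and Psma8, the testis form, unmarked. Each of the 5 groups was marked more often than other genes (exact adjusted p = 0.000125, 0.000474, 0.0104, 3.44e-11 and 5.85e-05 in the same order). Against CpG-matched lists the acetylation genes kept their call (permutation adjusted p = 0.0027), which they lost when only gene 5′ ends were used (exact adjusted p = 0.0569). The other 4 groups lost theirs, with CpG-matched adjusted p of 1, 0.369, 0.294 and 0.123. Cell cycle and immediate early genes were already at 100%, beside matched shares of 96.0 and 89.5%, so no higher share could have kept their calls. The lowest adjusted p over the 10 alternatives was 5.41e-05, 0.000225, 0.00557, 3.82e-12 and 2.24e-05 in the same order. Olfactory receptor genes, expressed mainly in olfactory neurons, were marked at 2 of 1123 (0.178%), Olfr94 (9.16) among them and Olfr1 not. Vomeronasal receptor genes were marked at 1 of 327 (exact adjusted p = 5.08e-145), Vmn1r4, which shares its peak with Nt5c3, and Vmn1r1 was not. Both receptor groups also lay under CpG-matched lists (permutation adjusted p = 0.0009 for each). In all, 9 of the 27 lists were marked more often than other genes, 8 less often, and 10 did not pass the threshold. Genes are not replicates, so these p-values describe the lists in this tissue and not variation between animals.

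**Figure D4:**
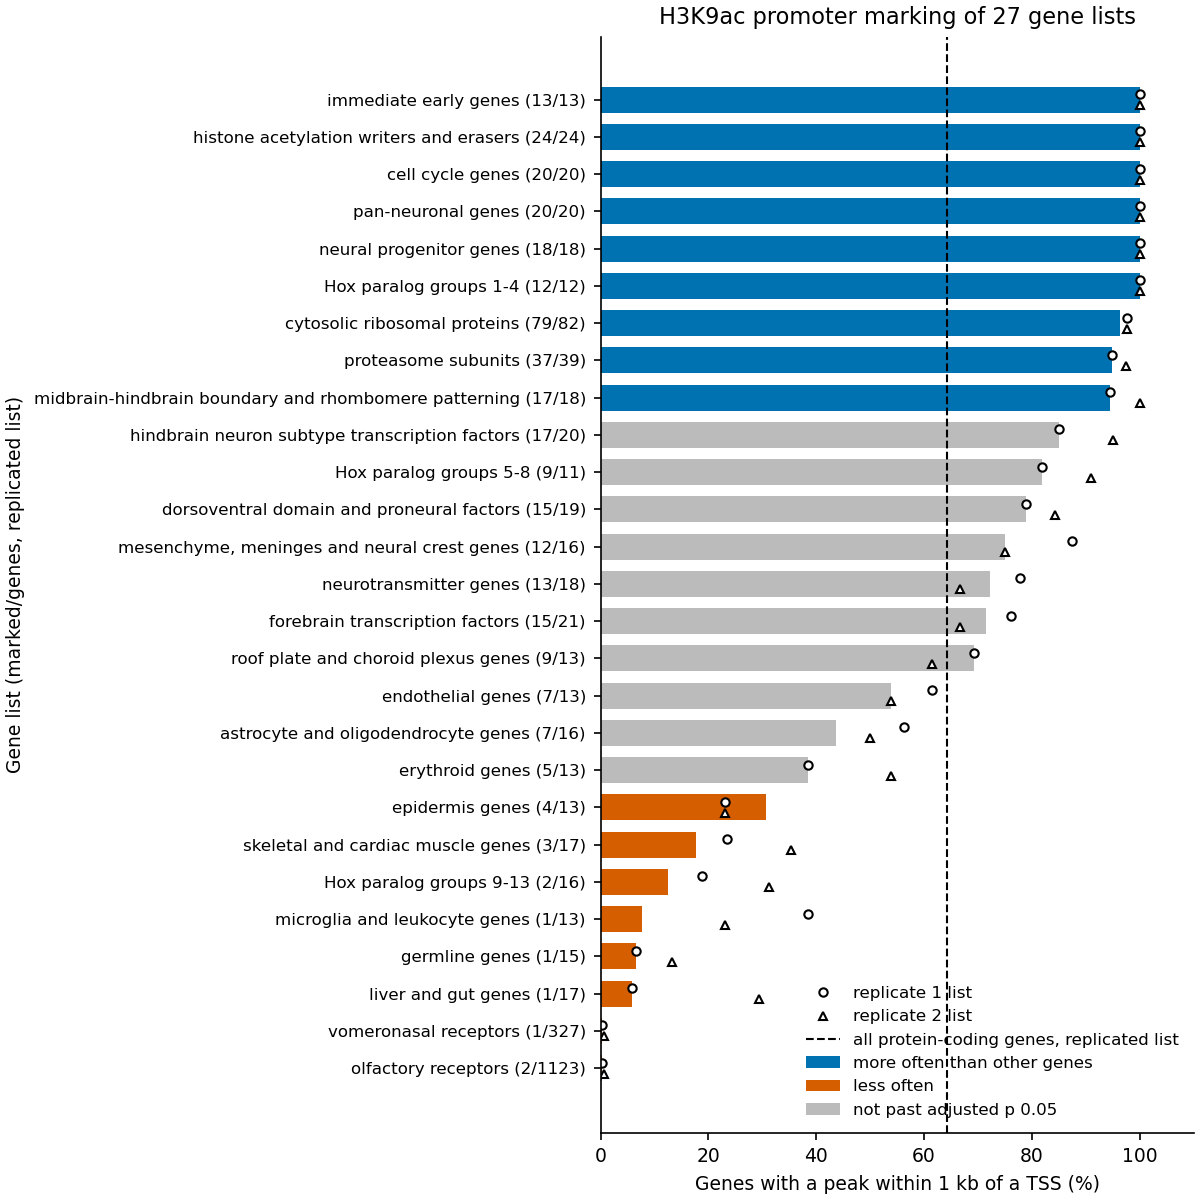
Share of genes with a peak within 1 kb of a TSS (x axis, %) for the 27 gene lists in the replicated list (bars), replicate 1 (circles) and replicate 2 (triangles), with the share of all protein-coding genes (64.3%) as a dashed line and bars coloured by the exact test against other genes. Bars run from 100% in 6 lists to 0.178% of olfactory receptors.

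The mark spread furthest around patterning, progenitor and anterior Hox genes. Within 5000 bp of the gene 5′ end, replicated peaks covered a median of 4933 bp at marked patterning genes, 4740.5 bp at Hox groups 1 to 4 and 4623 bp at progenitor genes, against 1817 bp over all marked genes. Pan-neuronal genes had 3159 bp, immediate early genes 3122 bp, Hox groups 5 to 8 had 3044 bp and ribosomal protein genes 2391 bp. Forebrain factors were narrow, with 1066 bp. At the genes marked in the replicated list, the replicate lists gave 4907 ± 137 bp for patterning genes, 4216 ± 421 bp for Hox groups 1 to 4, 4121 ± 23.0 bp for progenitor genes and 836 ± 233 bp for forebrain factors (mean ± SD, n = 2). The protein-coding genes with the most covered bases were the interneuron factor gene Lhx1 and the Hox cofactor gene Meis2 (both 10001 bp, the whole window), then Mex3a (9876 bp), the histone demethylase gene Kdm6b (9862 bp), the inhibitory transmitter transporter gene Slc32a1 (9854 bp), Lhx5 (9842 bp), the cerebellar and dorsal factor gene Zic1 (9804 bp), Hoxa2 (9796 bp), Tnrc18 (9795 bp) and Hoxb3 (9757 bp). Of 19 lists with at least 5 marked genes, 7 were wider than random lists of marked genes and 1 narrower. The permutation adjusted p was 0.00095 for patterning, Hox groups 1 to 4, progenitor and pan-neuronal genes, whose raw p of 0.0002 was the smallest that 10000 random lists can give. It was 0.00228 for ribosomal protein genes, 0.00887 for immediate early genes, 0.0347 for forebrain factors and 0.0399 for Hox groups 5 to 8, and the other 11 lists did not pass. The patterning and progenitor lists passed under all 8 alternatives (highest adjusted p 0.00127 for each).

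Several calls on breadth depended on the window or the comparison. Within 2000 bp, Hox groups 1 to 4 (permutation adjusted p = 0.714), pan-neuronal genes (0.130) and immediate early genes (0.101) were no longer called, while their lowest values over 8 alternatives were 0.000633 each. Immediate early genes also missed the threshold in the replicate 1 list (0.0933). Ribosomal protein genes were no wider than genes with promoter peaks of the same enrichment (permutation adjusted p = 0.956, lowest 0.000767). Hox groups 5 to 8 kept their call in 2 of 8 alternatives: the median was 1966 bp over the 9 genes marked in the replicate 1 list (0.559) and 1208 bp over the 10 marked in the replicate 2 list (0.339), where the direction turned, as it did within 2000 bp (0.0851). Over the 9 genes marked in the replicated list, the replicate 2 median was 1775 bp, against 1594 bp for all genes marked in replicate 2, so the turn in that list came with the change of genes. The forebrain call was lost within 2000 bp (permutation adjusted p = 0.095) and against lists matched on neighbouring promoters (0.0803), and against lists matched on peak enrichment the direction turned to 230 bp wider (0.421, lowest over 8 alternatives 0.00228). Subtype factors, not called here (permutation adjusted p = 0.303), were called wider around the best-covered TSS of each gene (0.00076), at −log10 q of at least 5 (0.00152) and at matched enrichment (0.0019), within a range up to 0.865. Neurotransmitter genes (permutation adjusted p = 0.0637) were called narrower within 2000 bp (0.0456) and around the best-covered TSS (0.0335), where acetylation genes were called wider (0.0335). At matched enrichment, dorsoventral and proneural factors (permutation adjusted p = 0.0169) and mesenchyme genes (0.049) were called wider and proteasome genes narrower (0.00109). The window sat on the outermost annotated 5′ end, so Gad1, Hoxa3, Hoxc5 and Hoxd3, marked at inner start sites, counted 0, 57, 0 and 264 bp.

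**Figure D5:**
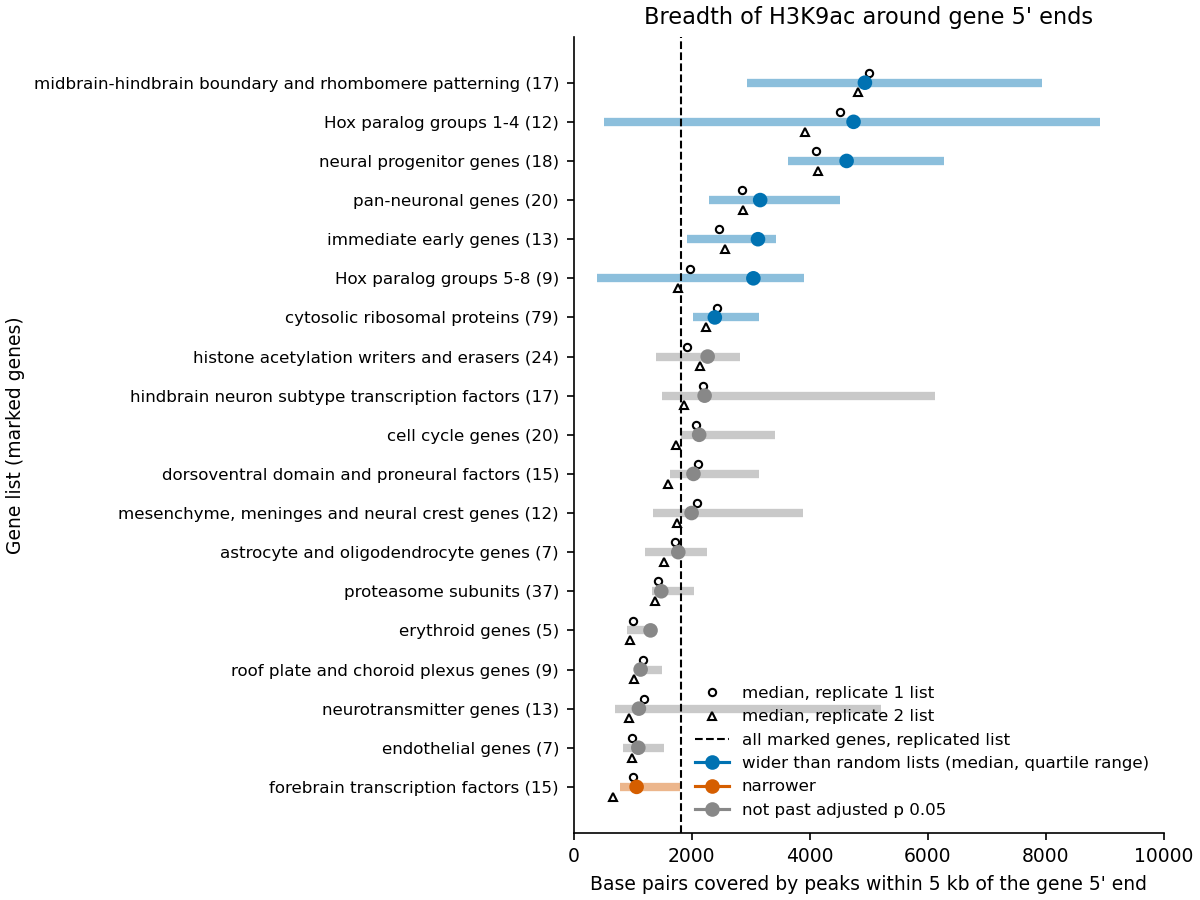
Base pairs covered by replicated peaks within 5 kb of the gene 5′ end (x axis) for 19 gene lists, as the median (filled point) and quartile range (bar) over marked genes, with the medians in replicate 1 (open circles) and replicate 2 (triangles) and that of all marked genes (1817 bp) as a dashed line. Patterning genes, Hox groups 1 to 4 and progenitor genes lie furthest right, at 4933, 4740.5 and 4623 bp.

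Distal peaks, more than 5000 bp from any protein-coding TSS, were most numerous per gene at the patterning and progenitor lists, and Hox groups 1 to 4, with 0.917 per gene, did not pass the test (permutation adjusted p = 0.497). Of the 11776 distal peaks, 10135 had a protein-coding TSS within 100 kb, and they were assigned to 4703 genes, a mean of 0.464 per protein-coding gene. Patterning genes had 79 such peaks over 18 genes (4.39 per gene) and progenitor genes 75 over 18 (4.17 per gene). Immediate early genes had 2.15 per gene, neuron subtype factors 1.95, and dorsoventral and proneural factors 1.84. Msi2 had 11 and Rbfox3 10, while olfactory and vomeronasal receptor genes had 0.0134 and 0.0306 per gene. The permutation adjusted p was 0.0108 for patterning, 0.0202 for progenitor genes, 0.0432 for immediate early genes, 0.0324 for subtype factors, 0.0396 for dorsoventral and proneural factors, and 0.0027 for both receptor groups, which had fewer. The other 20 lists did not pass. The single replicate lists hold more weak distal peaks and gave 8.22 and 8.06 per patterning gene and 7.61 and 9.28 per progenitor gene, against 1.16 and 1.44 over all genes. Patterning and progenitor genes passed in all 7 alternatives (highest adjusted p 0.0108 and 0.0202). Against lists matched on the distance to neighbouring genes, the calls on dorsoventral and proneural factors (permutation adjusted p = 0.169, lowest 0.0126), subtype factors (0.112, lowest 0.0117) and immediate early genes (0.081, lowest 0.0121) were lost. Away from the start sites of all gene types the subtype factors (0.054) and immediate early genes (0.232) were not called, nor were immediate early genes with a maximum of 1000000 bp (0.058) or in the replicate 1 list (0.0616). Pan-neuronal genes had 1.25 per gene (permutation adjusted p = 0.133) and were called in the replicate 2 list (0.0121), the replicate 1 list (0.0252) and with a minimum of 2000 bp (0.0312), within a range up to 0.364. Hox groups 9 to 13 had 0 distal peaks (permutation adjusted p = 0.117) and were called lower in the same 3 settings (0.0054, 0.0408 and 0.0312), and germline genes, also with 0 (0.133), in the replicate 1 list (0.0256) and with a minimum of 2000 bp (0.0373). Their highest adjusted p over 7 alternatives was 0.492 and 0.589.

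Of the 10 strongest distal peaks, 8 lay within 1000 bp of a start site of a non-coding gene or transcript. The strongest, 16.4 kb from the start of the chromatin remodeller gene Chd2 (chromosome 7, 73555957 to 73558619, enrichment 38.6), covered the start of 1810026B05Rik. The next lay over Malat1, an abundant nuclear non-coding RNA, with Scyl1 as the nearest protein-coding gene (chromosome 19, 5795904 to 5802672, enrichment 32.0). A peak of 19832 bp, 78.0 kb from the start of Mef2c, a factor of neuronal differentiation, covered the start of C130071C03Rik, the non-coding gene that contains Mir9-2 (chromosome 13, 83714665 to 83734496, enrichment 30.4). It was split in the replicate lists, with widest parts of 14432 and 10363 bp. A peak nearest to Ythdf1 lay at Mir124a-3, a gene of the neuronal microRNA miR-124 (28.3), and one nearest to Gpc5 at Mir17hg, the host of the miR-17 to miR-92 cluster (27.3). Gigyf1 (30.6), Ern1 (28.1) and Smim15 (26.1) were the protein-coding genes nearest to 3 others, and the peaks nearest to Rnf38 (27.9) and Nanos3 (26.0) had no non-coding start site within 1000 bp. Smim15 lay 155.5 kb from its peak, which was within 1000 bp of a start of Zswim6. Zswim6 counts as non-coding here only because the annotation used types it as a processed transcript. Of all distal peaks 10.8% lay within 1000 bp of a non-coding TSS, against 3.21 ± 0.135% of shuffled distal peaks (mean ± SD, 20 shuffles). Of the strongest 1210 by enrichment the share was 32.0%, for which no shuffles of their own were run.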

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

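The tests of the first 3 patterns were set down before their results were seen, and the shuffles of the weak pooled peaks were added afterwards. With 1 group of samples, no biological explanation was tested against another group.

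Hox groups 1 to 4 were marked at 12 of 12 genes and groups 9 to 13 at 2 of 16. Promoter CpG content argues the other way, since CpG-matched lists had a mean of 15.2 of 16 genes marked and at least 11, and the share with as few as groups 9 to 13 was put at 0.009999%, the smallest that 10000 lists can give. Weak peaks left out of the replicated list do not account for the difference, which held in all pooled peaks (12 of 12 against 6 of 16, exact p = 0.000883). It also held within 500 bp of the gene 5′ end (11 of 12 against 2 of 16, exact p = 5.38e-05). That window does not remove all sharing between neighbours, since Hoxd3 and Hoxd4 have nearly the same 5′ end and the same peak there. When genes with shared promoter windows were left out, a setting added afterwards, 11 of 11 and 2 of 16 were marked. No test between these 2 counts was run. Both exact tests count neighbouring genes of a cluster as independent. One hypothesis, among others not examined, is that the mark may follow the anterior limits of Hox expression in the hindbrain. These data, with no expression values and no other tissue, do not test it. Groups 5 to 8, marked at 9 of 11 genes, were not part of these tests.

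Forebrain transcription factors carried the mark at 15 of 21 promoters in hindbrain tissue. Promoter CpG content may suffice for that number, since 99.93% of CpG-matched lists had at least 15 marked, with a mean of 18.8. Cells of neighbouring forebrain tissue in the dissection also stay open: the factors were marked more often than muscle, liver and gut and posterior Hox genes of at least 0.555 observed over expected CpG, the lower quartile of the factors (71.4% against 31.3%, exact p = 0.02198). That value does not favour such cells: it would arise equally if neural cells of the hindbrain keep such promoters acetylated, and it also reflects how seldom the comparison genes were marked. The unmarked comparison genes included Hoxa11, Hoxa13, Hoxc9 and Hoxd13. The exact test thus partly repeats the Hox result above and counts clustered genes as independent. The CpG limit was applied to the comparison genes only, and all 21 factors were used. Against their own CpG-matched lists the muscle, liver and gut and posterior Hox genes had differences of -34.7, -37.9 and -82.6 points, and the forebrain factors -18.3 points. No forebrain gene stands in another list, and how many of them hindbrain cells express was not measured here.

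The 47 marked genes of Hox groups 1 to 4, patterning and progenitor lists had a median of 4856 bp covered. Random lists of marked genes had a median of 1905 bp when matched on promoter CpG content, 1702 bp when matched on the number of neighbouring promoters and 1875 bp when matched on the enrichment of the promoter peak. The permutation p was 0.00020 in each of the 3 tests, the smallest they can give, so none of these, matched singly, accounts for the breadth as a whole. These 3 lists were the widest of all tested lists in the same data. The draws also treat genes as independent, although the windows of neighbouring Hox genes overlap. The p-values may therefore overstate the evidence, and the 3 properties were not matched together. Sequencing depth and the merging of peaks by the authors' caller were not examined.

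In the pooled list, 16234 peaks (20.6%) overlapped no peak of either replicate list, and 402 of them were in the replicated list. They were narrow and weak, with a median of 200 bp and an enrichment of 2.48 (maximum 4.04), and 7.55% had a promoter summit, against 2.72 ± 0.143% of their shuffles (mean ± SD, 20 shuffles). Among long non-coding RNA genes more than 5000 bp from any protein-coding TSS, 752 of 7434 (10.1%) had a replicated peak at a start site, 984 in the replicate 1 list and 1084 in the replicate 2 list. On unplaced scaffolds, 6 replicated peaks were listed, with an enrichment of up to 10.2.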

How the results depend on the processing

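Alternatives added after the data were seen were start sites of all gene types for distal peaks, lists without shared promoter windows, and breadth matched on neighbouring promoters, matched on enrichment or taken at the best-covered TSS. The Hox difference kept its direction and its call in all 8 alternatives (62.5 to 93.8 points, exact p 4.27e-07 to 0.000883). Among the calls on gene lists, all 27 held for pooled peaks in both replicates, and 17 of 27 with CpG matching, where 8 were lost and 2 lists that did not pass were called less often than their matched lists. Unknown read depth limits what weak peaks can show.

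At −log10 q of at least 5 there were 25989 pooled, 21810 replicate 1 and 19187 replicate 2 peaks, and 41602 replicate 2 peaks at 2. The share of replicate 1 peaks found in replicate 2, and the reverse, was 42.0 and 39.8% for 50% of the peak, 45.2 and 41.3% for 50% of either peak, 33.7 and 28.9% for reciprocal 50%, 42.4 and 39.7% for the summit, 56.98 and 64.6% at −log10 q of 2, 78.6 and 91.7% at 5, 48.1 and 50.6% for equal numbers of peaks, and 84.7 and 88.2% for the strongest 20000. The base-pair Jaccard was 58.2, 70.6, 49.6 and 71.7% for the last 4. The promoter share of summits was 29.8 to 32.7% with a replicate left out, 26.5% in all pooled peaks, 56.3% in pooled peaks found in both replicates, 62.8% at −log10 q of 5, 41.4% at 500 bp, 55.3% at 2000 bp and 39.96% at gene 5′ ends. In the same order, marked genes were 65.7 to 66.1%, 67.3, 63.2, 62.5, 63.7, 65.1 and 61.2%.

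Lists marked more often fell from 9 to 3 with CpG matching. That test had little or no room to call lists whose matched share was already near 100%. Lists with wider marking fell from 7 to 3 within 2000 bp. Narrower lists went from 1 to between 1 and 5 with a replicate left out, where more lists had 5 marked genes, to 0 with neighbour matching and to 2 at the best-covered TSS. Lists with more distal peaks went from 5 to 2 with matched neighbour distance and to 3 away from all start sites, and those with fewer from 2 to between 3 and 4 with a replicate left out and to 4 at a minimum of 2000 bp. With CpG matching the marking difference turned in 6 lists: to -18.3 points for forebrain factors and -15.1 for dorsoventral factors, and, passing in neither setting, to -10.3 for Hox groups 5 to 8, -10.7 for subtype factors, 8.55 for erythroid and 0.0838 for astrocyte and oligodendrocyte genes. The breadth difference of Hox groups 5 to 8 was -386.5 to 290 bp with a replicate left out and -809 bp within 2000 bp, and that of forebrain factors was 230 bp with matched enrichment. Matching raises the comparison share for CpG-rich lists by construction, and for the other changes the cause was not tested.

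Other differences that turned passed in neither setting. In marking, in points, they were those of Hox groups 5 to 8 (-6.61), neurotransmitter (-0.0430) and roof plate genes (-7.31) at gene 5′ ends, and of glial genes (1.49) in all pooled peaks. Those of forebrain factors and roof plate genes were -1.34 and -1.70 for pooled peaks in both replicates, -0.614 and -0.980 at −log10 q of 5, and -6.54 and -2.14 at 500 bp, and that of roof plate genes was -4.58 to 3.55 with a replicate left out. In breadth, in bp, they were those of dorsoventral factors (-21), glial (456) and erythroid genes (10) with CpG matching, of glial (6) and mesenchyme genes (-97) within 2000 bp, of glial genes (43) with neighbour matching, and of glial (475), endothelial (93) and erythroid genes (12) with matched enrichment. With a replicate left out that of dorsoventral factors was -18 to 428.

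In distal peaks per gene, with a replicate left out, they were those of neurotransmitter (-0.230 to 0.608), endothelial (0.297 to 0.704), microglial (-0.357 to 0.0749), muscle (-0.268 to 0.153), acetylation (0.264 to 0.462) and ribosomal protein genes (-0.452 to 0.01195). At −log10 q of 5 they were those of roof plate (-0.0759), endothelial (0.0752) and muscle genes (0.0676), and at a minimum of 2000 bp those of Hox groups 5 to 8 (0.108), neurotransmitter (0.0950) and acetylation genes (0.251). They were those of microglial (0.0812) and ribosomal protein genes (0.133) at a maximum of 1000000 bp, and of Hox groups 5 to 8 (0.2095), roof plate (-0.0751) and ribosomal protein genes (0.111) with matched neighbour distance. Away from all start sites they were those of endothelial (0.0015), microglial (0.00552) and acetylation genes (0.0694). The cause was not tested.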

Other observations

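Genes of microRNAs of the nervous system lay inside some of the widest peaks, an observation made after their values were seen and not tested. All 6 genes of miR-9, a microRNA of neural progenitors, and miR-124, a microRNA of neurons, lay inside a peak of the replicated list and of each replicate list, more than 5000 bp from any protein-coding TSS. The peaks of Mir9-1 (15739 bp, chromosome 3, 88206568 to 88222306, enrichment 17.5), Mir9-3 (13803 bp, chromosome 7, 79499004 to 79512806, 21.6) and Mir124a-1 (10010 bp, chromosome 14, 64585168 to 64595177, 21.4) were among the 12 replicated peaks of at least 10 kb. Those of Mir124a-2, Mir124a-3 and Mir9-2 were 5620, 6586 and 4132 bp wide, wider than at least 99.1% of replicated peaks. A wide peak is also more likely to hold any given gene. Of 2202 annotated microRNA genes, 245 (11.1%) lay in a peak. Of the 12 widest peaks, 5 held no outermost 5′ end of a protein-coding gene. They were the 3 named here, the one at C130071C03Rik, and one of 12133 bp on chromosome 11 (98959325 to 98971457). All but the chromosome 11 peak lay more than 5000 bp from any protein-coding TSS. Whether that peak covers an inner start site of a protein-coding gene was not examined. Replicate lists split several of these, with widest parts of 12330 and 6153 bp at Mir9-1 and 7904 and 4884 bp in the chromosome 11 peak. Peaks with coding 5′ ends included those of Meis2 (17453 bp) and Lhx1 (12080 bp), with widest parts in the replicate lists of 13750 and 15806 bp and of 11436 and 10768 bp.

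Gene families, taken by symbol stem after the data were seen, split into broad classes. Of 111 stems with at least 20 genes, 52 were marked more often than other genes, 33 less often and 26 neither (two-sided Fisher exact tests, Benjamini-Hochberg), with no matching on CpG content. All 49 mitochondrial ribosomal genes of the Mrpl stem, 36 centrosomal Cep genes, 35 Vps genes of membrane sorting, 30 Mediator genes, 28 RNA polymerase (Polr) genes and 20 semaphorin genes, which guide axons, were marked. None of the 42 beta-defensin (Defb), 34 Rhox, 25 prolactin-family (Prl), 22 major urinary protein (Mup) or 21 late cornified envelope (Lce) genes was. Neither was any of 22 genes of the protocadherin beta cluster, which encodes neuronal adhesion molecules. Among 8741 genes in the 4 CpG-richest deciles, 178 (2.04%) were unmarked. Of 97 stems tested there, 3 passed: the protocadherin alpha entries, 11 of 11 unmarked (exact adjusted p = 8.89e-18), histone (Hist) genes, 8 of 61 (0.000958), and predicted genes of the Gm stem, 28 of 105 (3.2e-22). The unmarked genes also included the developmental regulators Nkx2-1, Nkx2-2, Nkx2-5, Cdx1, Cdx2 and Sim1. Whether reads could be placed uniquely in families of similar genes was not examined. A missing peak in them need not mean a missing mark.

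On chromosome X, 442 of 948 protein-coding genes (46.6%) were marked, against 65.7% on autosomes (two-sided Fisher exact p = 1.49e-31). CpG-matched lists had a mean of 54.9% marked, above the X chromosome value (permutation p = 0.0002, the smallest that 10000 lists can give). The pools were of mixed sex, and effects of X copy number or inactivation on peak calling were not examined. Of 183 genes on chromosome Y, 3 were marked, and unique placement of reads was not examined there either. The gene with the most distal peaks was Gse1, with 73, followed by Cstad with 32 and the ephrin receptor gene Ephb2 with 25.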
